A study of Mus musculus with 6 samples.

How the data were processed

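Nuclei were isolated by the submitters from frozen cortex of 7.5-month-old mice, sorted as NeuN-negative (50000 per sample) and loaded to target 10000 nuclei per library, with equal numbers from male and female mice (5000 each), on the 10x Genomics 3' v3 chemistry. There were 6 libraries in 3 groups of 2. The authors deposited 1 matrix of raw UMI counts per gene and nucleus for each library, not normalized. The submitters' processing notes name Cell Ranger 6.1.2 and mm10, and the file headers give 6.1.2 for 5 libraries and 5.0.1 for 5xFAD-P522R replicate 3. Whether reads in introns were counted is not stated. The smallest barcode total was 500 to 502 UMIs per library, so barcodes had been selected before deposit. Whether replicates 2 and 3 are separate sets of animals is not stated, so p-values measure the spread between libraries.

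Libraries held 13783, 10082 and 10098 barcodes (replicate 2 of 5xFAD, 5xFAD-M28L and 5xFAD-P522R) and 9456, 9269 and 9999 (replicate 3, same order). Their UMI totals were 72288942, 64761320 and 68221934, then 61079348, 53326947 and 61982158. Matrices were joined to 32285 genes, with 78 repeated symbols kept apart by their identifiers. Nuclei with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept, which left 62651. Doublets were called per library with Scrublet through scanpy 1.11.5 at an expected rate of 0.08. Its automatic threshold marked under 0.5% of nuclei in 3 libraries, and a common threshold of 0.277, the median of the other 3, was then used for all. The 3464 called doublets (4.68% to 6.56% per library) were removed after clustering, leaving 59187 nuclei.

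All passing nuclei were clustered with 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9), which gave 45 clusters. A cluster took the cell type with the largest share of markers higher than in other clusters, from marker lists fixed beforehand. It needed at least 3 markers, a share of 0.4 (0.25 for neurons), under 40% called doublets and, among its first 10 genes, no more markers of another class than of its own. These shares and bounds were set after looking at the clusters. There were 12 clusters left unnamed, and 57284 nuclei lay in named ones. The 7919 microglia-like nuclei were clustered again with 1000 genes, 15 components and resolution 0.5, and named from state markers (at least 3 and a share of 0.3, log2 fold of 0.58 or more), bounds that were also set after looking. Cluster names end in "-like" because they rest on markers alone.

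UMIs were summed per library and cell type where every library had at least 20 nuclei. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM, quasi-likelihood F-test, two-sided). All 6 libraries were in 1 fit with no replicate term, and p-values were adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. The 3 contrasts were M28L against 5xFAD, P522R against 5xFAD and P522R against M28L. The contrasts share groups and are not independent. Shares of cell types and of microglia clusters were tested with the same tool on numbers of nuclei, with the library's nuclei as the total, adjusted over types or clusters and contrasts. An exact permutation test of 2 against 2 libraries cannot go below 0.333 and was not used, and 33.3% of genes separate such groups by chance. T cells were too few for a test of genes. Means and SDs of genes are of TMM-normalized CPM.

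Before the data were examined, 31 gene lists, the marker lists, the tests, the alternatives of the main results and the rule for naming genes were fixed. Lists cover microglial states and functions, energy metabolism, states of other glia and of vessels, transcripts of neighbouring cell types, RNA quality and sex. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over lists and contrasts (and cell types, outside microglia), and by camera with an estimated correlation and fry as alternatives. Several lists share genes. The naming rule took Plcg2, then up to 12 genes per direction and contrast in microglia, filled by the smallest unadjusted p where fewer passed, up to 4 per direction that passed in other types, and up to 4 members of each list. Sex-linked genes and unnamed gene models are not named by that rule. A few genes that the rule names are not reported here. Prom1 was among the named genes in committed oligodendrocyte precursors and is left out, since it had no counts in 5xFAD and no fold can be given.

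Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts or a minimum of 50, fits of only the 4 libraries compared, a replicate term, at least 1000 UMIs per nucleus, called doublets kept, cell types at resolution 2 (60 clusters), microglia clusters at resolution 1, shares without neurons and unnamed nuclei, clustering without called genes (2), and each library left out in turn. Where that leaves 1 library in a group, it is assumed to vary like the others. Added after seeing the data were fits of Xist-positive nuclei alone, of Y-positive nuclei alone and of single microglia clusters, and clustering without the 2470 genes of unadjusted p under 0.05. A nucleus was called Xist-positive with at least 1 UMI of Xist and none of 4 Y-linked genes, and Y-positive the other way round. These are pools of nuclei, not separate animals. Nuclei were also thinned to 1000 UMIs each. Intervals on shares are 95% Clopper-Pearson intervals.

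The steps were tested on simulated data with the means and spread of the microglia counts. Of 100 genes changed by 2-fold, 72 and 71 were recovered in the contrasts of the changed group, and of 100 changed by 4-fold, 94 and 97. In these runs 18 and 20 unchanged genes were called, and 3 in a contrast with no changed gene. False calls were thus clearly more frequent than the threshold's nominal share. A contrast with 1 call lies within the number called where nothing had changed. A shifted list was found with 0 false lists. Genes were simulated independently of each other, so this does not test the preset correlation of camera where members of a list move together. Coordinates are from the GRCm38 annotation (gencode vM21), used for nothing else. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.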

Results

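The data are 6 single-nucleus RNA-seq libraries from the cortex of 7.5-month-old mice, prepared from nuclei sorted as negative for the neuronal protein NeuN. By their labels all groups are on 5xFAD, a transgenic background that gives amyloid plaques. The libraries fall into 3 groups of 2: 5xFAD alone, 5xFAD with the M28L variant of phospholipase C-γ2 (5xFAD-M28L), and 5xFAD with its P522R variant (5xFAD-P522R). Both libraries of a group carry the replicate numbers 2 and 3, and each library pooled nuclei of male and female mice. Total UMIs (unique transcript molecules) per library ranged from 53326947 to 72288942, over 9269 to 13783 barcodes, with medians of 3842 to 4973 UMIs per barcode. 5xFAD replicate 2 had the most barcodes and the lowest median. Values below are from 2 libraries per group (n = 2), fold changes are on the log2 scale with their standard error (SE), and intervals on shares of nuclei cover counting error only.

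Clusters carried markers of oligodendrocytes, microglia, oligodendrocyte precursors (OPCs), astrocytes, neurons, fibroblasts of the vessels and meninges, pericytes, endothelial cells, border macrophages, committed oligodendrocyte precursors and T cells. Oligodendrocyte-like nuclei made up 47.8% ± 3.61 (SD, n = 2) of nuclei in 5xFAD, 55.1% ± 0.965 in 5xFAD-M28L and 59.4% ± 0.962 in 5xFAD-P522R. Microglia-like nuclei, the immune cells of the brain, made up 14.6% ± 6.46, 14.1% ± 3.06 and 12.4% ± 4.34. Neuron-like nuclei remained at 7.95% to 9.51% on average after the sort, which sets their share. The number of microglia-like nuclei per library ranged from 880 to 1723, and their summed UMIs from 3445783 to 6934092.

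Plcg2 (ENSMUSG00000034330), the gene that carries both variants, encodes an enzyme that relays signals from microglial surface receptors such as TREM2. It lies on chromosome 8 from 117498291 to 117635142 of GRCm38, on the plus strand. In microglia-like nuclei Plcg2 had 409 ± 4.56 normalized CPM (UMIs scaled to a common library size, ± SD, n = 2) in 5xFAD, 476 ± 48.0 in 5xFAD-M28L and 446 ± 19.2 in 5xFAD-P522R. Neither variant passed against 5xFAD, although both libraries of each variant lay above both 5xFAD libraries: the log2 fold change was 0.22 (SE 0.095, adjusted p = 0.784) for M28L and 0.13 (SE 0.095, adjusted p = 0.684) for P522R. Between the variants it was −0.09 (SE 0.095, adjusted p = 0.846), and 0.016 when 5xFAD-M28L replicate 3 was left out. Border macrophage-like nuclei had 168 to 306 CPM of Plcg2 per library (here not normalized), and oligodendrocyte-like nuclei, which should lack it, had 1.26 to 3.55.

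The series title asks how variants of this enzyme change microglia, and the variants were first compared with each other. Several genes of disease-associated microglia, the plaque-responding state, had higher values in both P522R libraries than in both M28L libraries, without passing singly. Gpnmb, a glycoprotein of lysosome-rich phagocytes, had 56.9 ± 32.4 CPM in P522R and 2.35 ± 0.773 in M28L, a log2 fold change of 4.53 (SE 0.632, adjusted p = 0.106). Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, had 30.6 ± 1.40 and 4.33 ± 0.703 CPM (2.80, SE 0.33, adjusted p = 0.0961). Dkk2, a secreted modulator of Wnt signalling, had 168 ± 16.9 and 23.7 ± 12.4 CPM (2.81, SE 0.37, adjusted p = 0.106). The log2 fold change was 3.50 for Dcstamp, which takes part in the fusion of macrophages, 2.75 for Mamdc2, 2.70 for the VEGF receptor Flt1 and 1.58 for Gas7, with adjusted p from 0.109 to 0.116. None of these genes passed the threshold over all genes. The gene that did was lower in P522R: Gpc5 (ENSMUSG00000022112), a proteoglycan abundant in astrocytes, fell from 204 ± 2.54 to 103 ± 2.30 CPM (−0.99, SE 0.092, adjusted p = 0.0282). Gpc5 lost its call without 5xFAD-M28L replicate 2 (adjusted p = 0.405) or 3 (0.294), and without 5xFAD-P522R replicate 2 (0.652) or 3 (0.698).

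**Figure D1:**
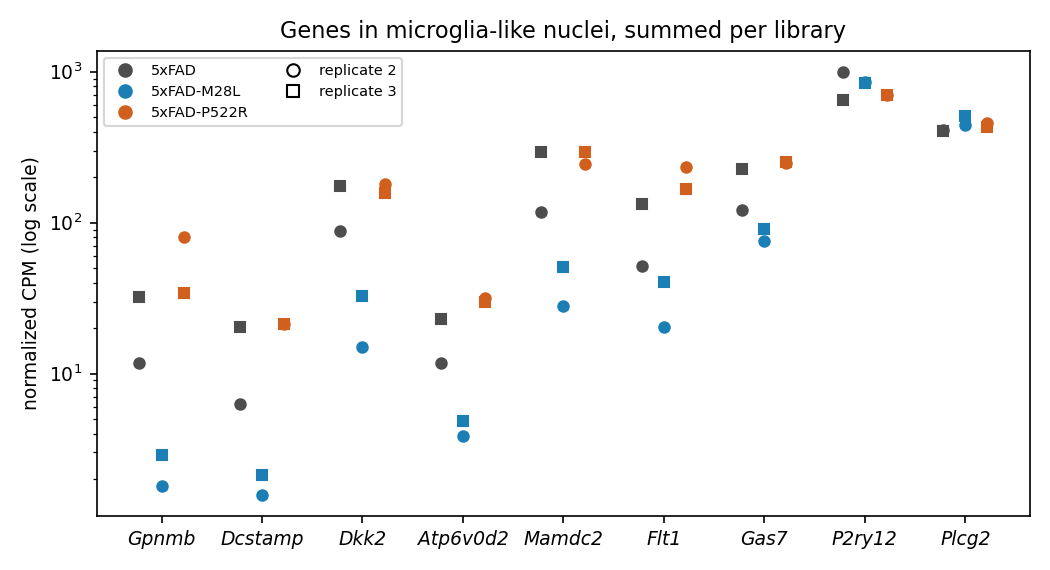
Normalized CPM (log scale) of 9 genes in microglia-like nuclei summed per library, 1 point per library. Both M28L libraries lie below all 4 others for Gpnmb, Dcstamp, Dkk2, Atp6v0d2, Mamdc2, Flt1 and Gas7.

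By edgeR, the 1 gene called between the variants stands beside 1132 of 13634 genes with an unadjusted p under 0.05, where 682 would be expected by chance. DESeq2 called 47 genes, 35 higher and 12 lower in P522R, and edgeR with a replicate term 65, 44 higher and 21 lower. When the fit held only the 4 libraries of the variants, edgeR called 293 genes, 187 higher and 106 lower. The count was 314 without 5xFAD replicate 2 and 310 without 5xFAD replicate 3, and 0 without any 1 of the 4 variant libraries. The spread between libraries that the test allows for (biological coefficient of variation) was 0.117 over all 6 libraries and 0.0831 over these 4.

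The lists of genes fixed beforehand were then tested as groups. Of 25 measured stage 2 genes of disease-associated microglia, 24 had a positive fold change in P522R against M28L, with a median of 0.65 and a mean of 1.10. Among them, log2 fold changes were 1.67 for Lpl (lipoprotein lipase), 1.42 for the fatty acid carrier Fabp5 and 1.06 for the integrin Itgax, with adjusted p of 0.325, 0.205 and 0.255. A list of such genes chosen for nuclei had a positive fold change for 21 of 24 members, with a median of 0.79. Adjusted over the list alone, 11 genes of the first list and 12 of the second passed, all higher in P522R, and 0 passed over all genes tested. Both lists passed camera with the preset correlation (adjusted p = 2.29e-29 and 2.94e-30), and neither did with an estimated correlation (adjusted p = 0.478 for both). The estimated correlations were 0.765 and 0.527, far above the preset value, so the test with the preset value overstates the evidence for both lists. The 19 homeostatic genes, which mark resting microglia, were all lower in P522R, with a median of −0.27 (adjusted p = 6.05e-09, or adjusted p = 0.478 with an estimated correlation). Among these were Csf1r, the receptor for microglial survival signals (−0.28, adjusted p = 0.449), and the phagocytic receptor Mertk (adjusted p = 0.285). Of the stage 1 genes, 9 of 9 were higher (adjusted p = 0.00385, or adjusted p = 0.478 with an estimated correlation), a call lost without 5xFAD-P522R replicate 2 (adjusted p = 0.0527).

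Genes of the cholesterol synthesis list were higher in P522R than in M28L in 19 of 19 cases, with a median of 0.64. They included the enzymes Msmo1 (0.88, adjusted p = 0.264) and Hmgcs1 (0.74, adjusted p = 0.419), and the regulator Srebf2 (0.82, adjusted p = 0.355). Adjusted over the list alone 6 of them passed, and camera gave adjusted p = 1.72e-11 with the preset correlation and adjusted p = 0.478 with an estimated one. Glycolysis (median 0.41, 13 of 17 higher, adjusted p = 0.00044), lipid handling (0.37, 16 of 23 higher, adjusted p = 0.00103) and lysosomal genes (0.16, 18 of 26 higher, adjusted p = 0.000989) were called in the same direction, and none with an estimated correlation (adjusted p = 0.478, 0.479 and 0.479). Within these, the lipid exporter Abca1 went the other way (−0.56, adjusted p = 0.345), while the lipoprotein receptor Scarb1 was at 0.67 (adjusted p = 0.432) and the lysosomal protein Cd68 at 0.47 (adjusted p = 0.559). Interferon response genes were lower in P522R in 25 of 28 cases, with a median of −0.15 (adjusted p = 0.00273, or adjusted p = 0.557 with an estimated correlation). That call was lost without 5xFAD-P522R replicate 2 (adjusted p = 0.0973). Oas2, a sensor of viral RNA, was at −0.95 (adjusted p = 0.381). Most interferon genes were lower in P522R in Xist-positive nuclei alone but higher in Y-positive nuclei alone (values under other observations). The pooled direction thus depends on the mix of sexes, and the difference between the sexes was not tested for the list. Phagocytic receptor genes had a median of −0.10 (adjusted p = 0.0263, or adjusted p = 0.478 with an estimated correlation), and lost the call without 5xFAD-M28L replicate 3 (0.342) or 5xFAD-P522R replicate 3 (0.361). The 28 genes of TREM2 and PLCG2 signalling were not called (median −0.05, 9 higher, adjusted p = 0.237), with Inpp5d, a phosphatase that opposes this pathway, at −0.33 (adjusted p = 0.312) and the kinase Syk at −0.32 (adjusted p = 0.419). Complement genes were not called (adjusted p = 0.0959), with C1qb at −0.46 and C1qc at −0.42.

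Markers of astrocytes moved with these groups in microglia-like nuclei. A list of 10 abundant astrocyte transcripts was lower in P522R than in M28L for 10 of 10 members, with a median of −0.95, and 8 passed adjusted over the list alone. The glutamate transporter Slc1a2 was at −0.91 (adjusted p = 0.106), and Gpc5 is a member. The list passed camera with the preset correlation (adjusted p = 1.69e-20) and with an estimated one (adjusted p = 0.0494), and fry gave adjusted p = 0.079. The wider list of homeostatic astrocyte genes had a median of −0.59 with 0 of 18 higher (adjusted p = 1.75e-23, 0.0494 with an estimated correlation and 0.00206 by fry). These were the lists between the variants that kept a call with an estimated correlation. The list of 10 transcripts had been fixed as a check of RNA from other cells. Astrocyte-like nuclei were also fewer in P522R, at 2.49% of nuclei on average against 6.52% in M28L. For these lists and for Gpc5, less RNA from astrocytes thus cannot be told apart from a change in microglia. Female nuclei, as marked by Xist, were 76.3% and 73.1% of the sexed microglia-like nuclei in P522R and 48.0% and 62.1% in M28L.

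For M28L against 5xFAD, the question is whether this variant changes microglia on the amyloid background. The same state genes were at lower values in M28L: Dkk2 at −2.47 (SE 0.368, adjusted p = 0.417), Atp6v0d2 at −2.03 (SE 0.339, adjusted p = 0.571), Mamdc2 at −2.38 (SE 0.4, adjusted p = 0.571) and Gpnmb at −3.25 (SE 0.667, adjusted p = 0.681). Without 1 library these 4 ran in turn from −3.152 to −1.863, −2.384 to −1.413, −2.879 to −1.556 and −3.727 to −2.274, each nearest to 0 without 5xFAD replicate 3. That fit leaves 5xFAD replicate 2 as the only 5xFAD library. Of its Xist-positive microglia-like nuclei, 3 of 454 lay in the disease-associated-like cluster described below. Oas2 was at 1.43 (SE 0.259, adjusted p = 0.571) and the synaptic adhesion gene Lrrtm3 at −0.93 (SE 0.12, adjusted p = 0.196). The 5xFAD libraries themselves differed widely in these genes, with 131 ± 61.1 CPM for Dkk2 and 21.8 ± 14.4 for Gpnmb. edgeR called 1 gene, among 864 with an unadjusted p under 0.05, 30 with a replicate term, and DESeq2 called 7. The gene was Tsix, the antisense RNA of Xist, which fell by 1.40 in M28L (SE 0.124, adjusted p = 0.0184). Tsix is sex-linked and outside the naming rule, and is named after its value was seen. The count was 143 without 5xFAD replicate 2, 58 without 5xFAD replicate 3 and 0 without any 1 of the other libraries.

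The TREM2 and PLCG2 signalling list was higher in M28L than in 5xFAD for 25 of 28 genes, with a median of 0.14. Its examples were small, with Inpp5d and Syk both at 0.23 (adjusted p = 0.784). The list passed camera with the preset correlation (adjusted p = 0.000264), but not with an estimated one (adjusted p = 0.367). The estimate was −0.002, below the preset value, yet the unadjusted p of camera went from 5.11e-05 to 0.0197. This loss thus does not come from a higher correlation between the genes, and its source was not tested. Interferon genes were higher in 24 of 28 cases (median 0.19, adjusted p = 1.81e-06, or adjusted p = 0.479 with an estimated correlation), with Ifi44 at 0.91 (adjusted p = 0.784). This call was lost without 5xFAD replicate 2 (adjusted p = 0.525). Homeostatic genes were higher in 17 of 19 (median 0.15, adjusted p = 0.00242), stage 2 disease genes lower in 18 of 25 (median −0.16, adjusted p = 1.92e-06) and those of the nuclei list lower in 16 of 24 (median −0.39, adjusted p = 7.61e-09). With an estimated correlation these gave adjusted p = 0.514, 0.504 and 0.479. Adjusted over the list alone, 6 stage 2 genes and 8 of the nuclei list passed. Without 5xFAD replicate 3 the signs of these 3 medians turned, to −0.01, 0.158 and 0.06, and none was called (adjusted p = 0.964, 0.224 and 0.729).

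Some lists of metabolism were called lower in M28L than in 5xFAD with the preset correlation only, as was that of ribosomal proteins. Ribosomal proteins and mitochondrial transcripts had been fixed as checks of RNA quality. Mitochondrial transcripts were not called (median −0.01, adjusted p = 0.628). For oxidative phosphorylation 26 of 30 were lower (median −0.27, adjusted p = 1.79e-06), with Cox7c, a subunit of cytochrome oxidase, at −0.46 (adjusted p = 0.784). For ribosomal proteins 27 of 30 were lower (median −0.19, adjusted p = 0.000119). This list was also lower in P522R microglia-like nuclei and in oligodendrocyte-like nuclei of both variants, so it is not particular to microglia or to M28L. For cholesterol synthesis 18 of 19 were lower (median −0.32, adjusted p = 7.36e-05), with Sc5d at −0.80 and Msmo1 at −0.66, each with adjusted p = 0.784. For glycolysis 16 of 17 were lower (median −0.20, adjusted p = 0.0123). With an estimated correlation none was called (adjusted p = 0.478 for oxidative phosphorylation and 0.479 for the other 3). Oxidative phosphorylation (0.0634) and ribosomal proteins (0.262) lost the call without 5xFAD replicate 2, cholesterol synthesis without 5xFAD replicate 3 (0.564), and glycolysis without 5xFAD-M28L replicate 2 (0.191). The median for glycolysis was 0.167 (adjusted p = 0.598) without 5xFAD replicate 3. MHC class I genes (median 0.21), phagocytic receptors (0.10) and abundant oligodendrocyte transcripts (0.27) were called higher, and disease-associated astrocyte genes (−0.18) lower, with adjusted p of 0.0142, 0.0142, 0.00293 and 0.00638. None of these was called with an estimated correlation (adjusted p = 0.479, 0.478, 0.504 and 0.479). Without 5xFAD replicate 2 the call was lost for MHC class I (0.226), phagocytic receptors (0.154) and oligodendrocyte transcripts (0.208). It was also lost for MHC class I without 5xFAD-M28L replicate 2 (0.399), for the other 3 without 5xFAD-M28L replicate 3 (0.311, 0.552 and 0.083), for phagocytic receptors without 5xFAD-P522R replicate 3 (0.0583) and for astrocyte genes without 5xFAD replicate 3 (0.457).

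For P522R against 5xFAD, the gene closest to the threshold was again Gpc5, at lower values in P522R (SE 0.092, adjusted p = 0.0733), followed by the ion channel Trpm3 at −1.04 (SE 0.119, adjusted p = 0.08). Other astrocyte genes were among the lowest, with Clu at −1.27 and Slc1a2 at −0.89 (adjusted p = 0.248 for both). On the other side were the phosphodiesterase Pde1a (1.14, SE 0.169, adjusted p = 0.248) and Samd4 (0.62, adjusted p = 0.292). Of the disease state genes, Gpnmb was at 1.28, Lpl at 1.04, Atp6v0d2 at 0.77, Itgax at 0.72 and Cd68 at 0.62, with adjusted p from 0.503 to 0.507. Without 1 library these 5 ran in turn from 0.585 to 2.254, 0.545 to 1.985, 0.416 to 1.396, 0.409 to 1.201 and 0.438 to 0.881, each highest without 5xFAD replicate 3. That fit, with its number of calls below, rests on 5xFAD replicate 2 as the only 5xFAD library. Of its Xist-positive microglia-like nuclei, 3 of 454 were disease-associated-like. edgeR called 0 genes, with 1291 at an unadjusted p under 0.05, and DESeq2 called 12. With a replicate term edgeR called 135, 33 higher and 102 lower. Gpc5 passed without 5xFAD replicate 2 (adjusted p = 0.00659) or 5xFAD replicate 3 (0.000805). The count was 833 without 5xFAD replicate 3, 1 without 5xFAD replicate 2 and 0 without any 1 of the other libraries.

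Stage 2 disease genes were higher in P522R than in 5xFAD in 24 of 25 cases (median 0.43, adjusted p = 4.36e-11) and those of the nuclei list in 20 of 24 (median 0.48, adjusted p = 1.57e-09). Lysosomal genes were higher in 21 of 26 (median 0.10, adjusted p = 0.000302), with the enzyme Gusb at 0.42 (0.281 to 0.583 without 1 library). Cholesterol synthesis was higher in 16 of 19 (median 0.28, adjusted p = 0.00595), with the enzyme Lss at 0.87. With an estimated correlation these 4 lists had adjusted p = 0.479, 0.479, 0.478 and 0.504. Cholesterol synthesis lost its call without 5xFAD replicate 2 (0.476) or 5xFAD-P522R replicate 3 (0.141). Homeostatic genes were lower in 16 of 19 (adjusted p = 0.00736, or adjusted p = 0.566 with an estimated correlation), with Gpr34 at −0.34 (−0.449 to −0.226 without 1 library) and Crybb1 at −0.75 (−1.173 to −0.228), and lost the call without 5xFAD replicate 2 (0.968, with a median of 0.055) or 5xFAD-P522R replicate 2 (0.107). Lipid handling (median 0.07, adjusted p = 0.0154, or adjusted p = 0.479 with an estimated correlation) lost its call without the same libraries (0.475 with a median of −0.004, and 0.324). TREM2 and PLCG2 signalling was not called (median 0.10, 19 of 28 higher, adjusted p = 0.0612). Oxidative phosphorylation (28 of 30 lower, adjusted p = 0.000302) and ribosomal proteins (24 of 30 lower, adjusted p = 0.00327) were called lower, but not with an estimated correlation (adjusted p = 0.479 and 0.514) nor without 5xFAD replicate 2 (0.0746 and 0.347).

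Transcripts typical of other cell types moved with P522R against 5xFAD in microglia-like nuclei. RNA carried over from those cells cannot be told apart here from a change in microglia. Abundant astrocyte transcripts were lower in 10 of 10 (median −1.31, adjusted p = 2.76e-27, 0.0494 with an estimated correlation, 0.0594 by fry), and 9 passed adjusted over the list alone. Homeostatic astrocyte genes had a median of −0.73 (adjusted p = 1.35e-20, 0.0494 with an estimated correlation, 0.00217 by fry). Abundant oligodendrocyte transcripts were higher in 10 of 12 (median 0.39, adjusted p = 4.77e-05) and neuronal ones in 13 of 16 (median 0.22, adjusted p = 0.000989). Myelin genes (median 0.30, adjusted p = 0.00234), blood-brain barrier genes (−0.39, adjusted p = 0.00385), disease-associated astrocyte genes (−0.22, adjusted p = 0.0164) and sex-linked genes (−0.48, adjusted p = 0.00105) were also called. With an estimated correlation these 6 lists had adjusted p = 0.479, 0.478, 0.538, 0.478, 0.484 and 0.478. Myelin lost its call without 5xFAD-P522R replicate 3 (0.551), and disease-associated astrocyte genes without 5xFAD replicate 3 (0.802, with a median of 0.087) or 5xFAD-P522R replicate 3 (0.499).

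Microglia-like nuclei were also clustered alone. A cluster with markers of disease-associated microglia held 38.2% (95% Clopper-Pearson interval 35 to 41.5) and 38.1% (35.6 to 40.6) of microglia-like nuclei in the P522R libraries. In the M28L libraries it held 10.2% (8.51 to 12.1) and 12.1% (10.5 to 13.9). In 5xFAD it held 12.4% (10.7 to 14.3) in replicate 2 and 35.2% (33.0 to 37.5) in replicate 3. The log2 ratio of P522R to M28L was 1.77 (SE 0.457, adjusted p = 0.0228 by edgeR), the 1 call among the clusters and contrasts. The call was lost with at least 1000 UMIs per nucleus (adjusted p = 0.0709), with doublets kept (0.0737) and at the other resolution (0.126). With doublets kept, 2 clusters of 2509 and 264 nuclei took the name in place of 1 of 1947. That setting thus tests a different set of nuclei. The genes that define this cluster also differ between the groups, so its size is not read as a change of state. With genes of an unadjusted p under 0.05 kept out of the clustering, a choice made on the outcome, the disease-associated-like cluster held 4074 nuclei in place of 1947, near the sum with an unnamed cluster of 2157. Its ratio of 0.306 (adjusted p = 0.862) is therefore that of a different cluster and does not test the first. The call was also lost without 5xFAD-M28L replicate 2 (adjusted p = 0.68) or 3 (0.448) and without 5xFAD-P522R replicate 2 (0.387) or 3 (0.388). Against 5xFAD the log2 ratio was −1.09 for M28L (SE 0.451, adjusted p = 0.213) and 0.68 for P522R (SE 0.443, adjusted p = 0.443). Without 5xFAD replicate 2 it was −1.642 for M28L and 0.114 for P522R. Without 5xFAD replicate 3 it was −0.136 for M28L and 1.62 for P522R. Both ratios thus depend on which 5xFAD library is kept. Such a fit holds 1 5xFAD library and takes its spread from the pairs of the variants. The 5xFAD pair, at 12.4% and 35.2%, differed more than those pairs, so only the ratios are given. In Xist-positive and Y-positive nuclei apart, the log2 ratio of mean percents was −0.245 and −1.952 for M28L, and 1.272 and −0.05 for P522R. The Xist-positive values include 5xFAD replicate 2 at 0.661%. The difference between the sexes was tested by edgeR as an interaction, with log2 values of 3.192 for M28L and 2.817 for P522R. Neither passed (adjusted p = 0.398 and 0.407). Median UMIs per microglia-like nucleus were 2721 in 5xFAD replicate 2 and 3475 to 3762 in the others.

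**Figure D2:**
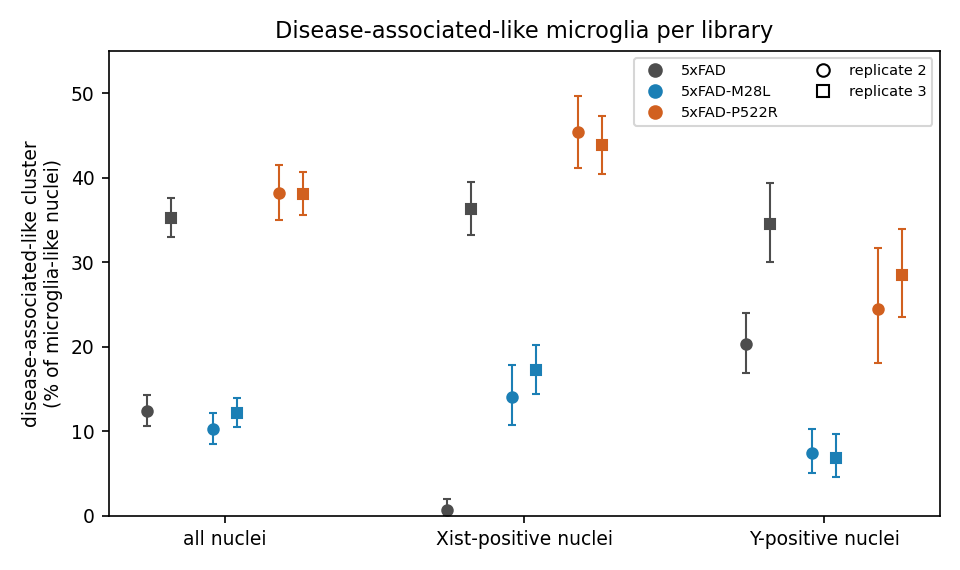
Percent of microglia-like nuclei in the disease-associated-like cluster per library, over all nuclei and over Xist-positive and Y-positive nuclei, with 95% Clopper-Pearson intervals. Xist-positive nuclei of 5xFAD replicate 2 lie at 0.661%, against 36.3% in 5xFAD replicate 3. The log2 ratio of P522R to M28L over all nuclei is 1.77, and 0.306 for the different, larger cluster (4074 nuclei against 1947) found without genes of unadjusted p under 0.05.

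The remaining cell types were tested to see whether the variants change other cells of the cortex. In committed oligodendrocyte precursor-like nuclei, M28L against 5xFAD had 9 calls by edgeR and 7 by DESeq2. The heparan sulfate enzyme Hs6st3 rose by 2.34 (SE 0.334, adjusted p = 0.00414), the guidance receptor Ephb1 by 1.70 (SE 0.256, adjusted p = 0.00414) and the myelin gene Mobp by 1.62 (SE 0.307, adjusted p = 0.0399). The receptor-associated Shisa9 changed by −0.96 (SE 0.181, adjusted p = 0.0399). All 4 lost the call without 5xFAD-M28L replicate 3, with adjusted p of 0.0658, 0.0744, 0.275 and 0.397 in that order, and edgeR then called 0 genes. Mobp and Shisa9 also lost it without 5xFAD-M28L replicate 2 (0.114 and 0.182), 5xFAD-P522R replicate 2 (0.0878 and 0.133) or 5xFAD replicate 3 (0.178 and 0.175), and Shisa9 without 5xFAD-P522R replicate 3 (0.0802). P522R had 0 calls here by edgeR and DESeq2 against 5xFAD (535 at an unadjusted p under 0.05) or M28L (416), where 382 would be expected by chance. Against 5xFAD edgeR called 18 genes without 5xFAD replicate 3, 3 without 5xFAD replicate 2 and 21 with a replicate term, and against M28L 0 to 7 without 1 library and 7 with a replicate term.

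In endothelial-like nuclei the astrocyte genes Gpc5 and Luzp2 were lower in both variants. Astrocyte transcripts were also lower in P522R in microglia-like and oligodendrocyte-like nuclei. Less RNA from astrocytes in these nuclei thus cannot be told apart from a change in endothelial cells. 5xFAD-P522R replicate 3 held only 24 endothelial-like nuclei. Against 5xFAD, Gpc5 changed by −3.78 (SE 0.289, adjusted p = 8.05e-05) in P522R and −1.72 (SE 0.228, adjusted p = 0.0205) in M28L, and Luzp2 by −2.99 (SE 0.281, adjusted p = 0.000462) and −2.10 (SE 0.236, adjusted p = 0.00678). The calls in P522R held without any 1 library. Those in M28L were lost without 5xFAD-M28L replicate 2 (0.133 for Gpc5 and 0.135 for Luzp2), 5xFAD-M28L replicate 3 (0.16 and 0.0876) or 5xFAD replicate 3 (0.163 and 0.0882). The glutamate receptor gene Gria4 rose by 2.11 in P522R (SE 0.299, adjusted p = 0.0274), and did not pass without 5xFAD replicate 2 (0.159), 5xFAD replicate 3 (0.176) or 5xFAD-P522R replicate 2 (0.14). Abundant neuronal transcripts were higher there in 15 of 15 cases (median 1.41, adjusted p = 8.57e-11, or adjusted p = 0.791 with an estimated correlation). In pericyte-like nuclei the nuclear RNA Malat1 changed by −0.55 in M28L (adjusted p = 0.00239) and −0.52 in P522R (adjusted p = 0.00467), and by DESeq2 neither passed. The M28L call for Malat1 was lost without 5xFAD-M28L replicate 2 (0.07). Pde10a, a phosphodiesterase, changed in P522R by −1.71 against 5xFAD (adjusted p = 0.0137) and −1.77 against M28L (adjusted p = 0.0211). Both of its calls were lost without 5xFAD-P522R replicate 3 (0.123 and 0.175), and the second also without 5xFAD-M28L replicate 2 (0.145) or 3 (0.156). With a replicate term no call for Malat1 (adjusted p = 0.0952 in M28L and 0.0803 in P522R) or Pde10a (0.0803 and 0.0621) remained.

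In neuron-like nuclei, P522R against 5xFAD had 14 calls by edgeR, 107 with a replicate term and 116 by DESeq2. The dopamine receptor Drd3 (1.92, SE 0.162, adjusted p = 0.0206), the transcription factor Isl1 (1.90, adjusted p = 0.0305), Stac (1.89, SE 0.107, adjusted p = 0.00474) and the receptor Gpr149 (1.64, adjusted p = 0.0314) were higher, and Tiam2 (−0.69, adjusted p = 0.036) and Rgs20 (adjusted p = 0.0434) lower, over all neuron-like nuclei together. Drd3, Stac and Gpr149 are among the leading genes of 1 neuron-like cluster, which held 15 and 9 nuclei in the 5xFAD libraries, 47 and 32 in M28L and 125 and 109 in P522R. Tiam2 is among those of another, with 214 and 93, 118 and 92, and 41 and 48. The mix of neuron clusters thus differed between the groups, and no gene was tested within a cluster. The calls depended on the libraries in the fit: edgeR called 0 genes without 5xFAD replicate 2, 1 without 5xFAD-P522R replicate 3, 2 without 5xFAD replicate 3, 4 without 5xFAD-M28L replicate 2, 5 without 5xFAD-M28L replicate 3 and 7 without 5xFAD-P522R replicate 2. Stac lost its call without 5xFAD replicate 2 (adjusted p = 0.0881) and kept it without each of the others. Against M28L edgeR called 1 gene, the gene model 2610307P16Rik (−1.51, SE 0.112, adjusted p = 0.0339), named after its value was seen and also a leading gene of the cluster that Tiam2 marks, and 0 without any 1 of the 4 variant libraries, while DESeq2 called 27 genes. The sort depletes neurons, and myelin genes were higher in these nuclei in P522R in 17 of 18 cases (median 0.60, adjusted p = 3.68e-11, or adjusted p = 0.791 with an estimated correlation).

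In oligodendrocyte-like nuclei, P522R against 5xFAD had 8 calls by edgeR and 87 by DESeq2. The genes that fell are ones astrocytes express: Slco1c1 (−1.84, adjusted p = 0.0473), Prex2 (−1.55, adjusted p = 0.0253) and the bicarbonate transporter Slc4a4 (−1.17, adjusted p = 0.0438). Less RNA from astrocytes in these nuclei cannot be told apart from a change in oligodendrocytes. Prex2 (−1.43, adjusted p = 0.0444) and Slc1a2 (−0.98, adjusted p = 0.0414) also fell against M28L. Abundant astrocyte transcripts were lower in 10 of 10 cases against 5xFAD (median −1.29, adjusted p = 6.4e-35, or adjusted p = 0.791 with an estimated correlation), and 8 passed adjusted over the list alone. edgeR called 0 genes for P522R against 5xFAD without 5xFAD replicate 2, 5xFAD-P522R replicate 2, 5xFAD-M28L replicate 3 or 5xFAD-P522R replicate 3, 1 without 5xFAD-M28L replicate 2 and 4 without 5xFAD replicate 3. Against M28L it called 0 without any 1 of the 4 variant libraries. Ribosomal protein genes were lower than in 5xFAD in 30 of 30 cases in M28L (median −0.37, adjusted p = 1.12e-11) and in P522R (median −0.40, adjusted p = 4.5e-17), and neither was called with an estimated correlation (adjusted p = 0.791 for both). M28L against 5xFAD had 0 gene calls by edgeR, 2065 genes at an unadjusted p under 0.05 (792 expected by chance) and 136 calls by DESeq2. With a replicate term edgeR called 989 genes for M28L and 930 for P522R against 5xFAD, and 158 between the variants.

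No gene was called by edgeR in OPC-like or astrocyte-like nuclei in any contrast. For M28L against 5xFAD, P522R against 5xFAD and P522R against M28L, the genes at an unadjusted p under 0.05 numbered 1770, 1633 and 799 in OPCs and 667, 1303 and 1030 in astrocytes. By chance 730 would be expected in OPCs and 684 in astrocytes. DESeq2 called 104, 20 and 0 genes in OPCs and 1, 20 and 20 in astrocytes, and edgeR with a replicate term 1050, 840 and 95 in OPCs and 30, 177 and 1 in astrocytes. Without 1 library the counts in OPCs were 0 to 33, 0 to 104 and 0 to 1, and in astrocytes 0 to 1, 0 to 285 and 0 to 203, the largest without 5xFAD replicate 3 in OPCs against 5xFAD and without 5xFAD-P522R replicate 2 in astrocytes for P522R. The absence of calls thus depends on the model and on the libraries. Border macrophage-like and fibroblast-like nuclei had no call by edgeR either. DESeq2 called 1 gene in border macrophages, between the variants, and 0 in fibroblasts. Genes at an unadjusted p under 0.05 numbered 169 to 213 and 345 to 576, where 247 and 513 would be expected by chance. In OPCs, interferon response genes were lower in P522R than in M28L in 20 of 20 cases, with Oasl2 at −1.12 (adjusted p = 0.809) and Ifit1 at −1.05 (adjusted p = 0.895). Camera gave adjusted p = 3.44e-12 for that list and adjusted p = 0.791 with an estimated correlation, and 3 genes passed adjusted over the list alone. In astrocytes, disease-associated genes were higher in P522R than in M28L in 19 of 21 cases (median 0.33, adjusted p = 0.000244) and homeostatic genes lower in 17 of 18 (median −0.23, adjusted p = 3.63e-08). With an estimated correlation both had adjusted p = 0.791. Examples were the lysosomal protease Ctsd at 0.68 (adjusted p = 0.627), the lipid carrier Apoe at 0.34 (adjusted p = 0.639), the water channel Aqp4 at 0.33 and Luzp2 at −0.42.

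In P522R against either group, the share of astrocyte-like nuclei had the largest log2 ratio, and in M28L against 5xFAD that of T cell-like nuclei, of which a library held 6 to 15 (0.91, adjusted p = 0.265). Astrocyte-like nuclei made up 10.2% and 8.43% of nuclei in the 5xFAD libraries, 7.08% and 5.97% in M28L, and 3.34% and 1.64% in P522R. The log2 ratio was −1.39 for P522R against M28L (SE 0.38, adjusted p = 0.163) and −0.52 for M28L against 5xFAD (adjusted p = 0.5). For P522R against 5xFAD the test by edgeR gave SE 0.385 and adjusted p = 0.0752. This became a call without 5xFAD-M28L replicate 2 or 3 (adjusted p = 0.0454 for both) and without 5xFAD-P522R replicate 2 (5.34e-05) or 3 (0.0157), and P522R against M28L became one without 5xFAD-P522R replicate 2 (−1.99, adjusted p = 0.000299). Means in 5xFAD, M28L and P522R were 2.03%, 1.63% and 0.801% for fibroblast-like, 1.03%, 0.772% and 0.504% for pericyte-like and 0.978%, 0.830% and 0.435% for endothelial-like nuclei. By edgeR 0 of the 33 share tests passed, with 6 at an unadjusted p under 0.05, while some passed with a replicate term (their number is given below). The number of passing shares was 8 without 5xFAD-P522R replicate 2 and 1 without 5xFAD-P522R replicate 3 or either 5xFAD-M28L library. Shares are of sorted nuclei, and a change in 1 type moves the shares of the others.

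**Figure D3:**
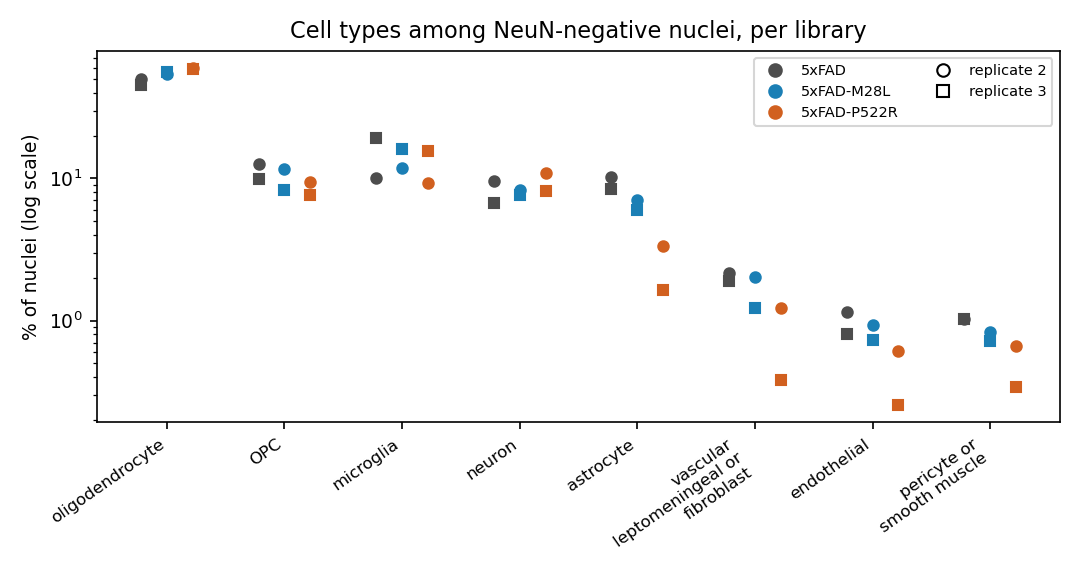
Percent of nuclei (log scale) of 8 cell types in each library, by group and replicate. Astrocyte-like nuclei are lowest in both P522R libraries, at 3.34% and 1.64%, against 5.97% to 10.2% in the other 4.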

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

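The tests of the whole-library fault, of the sex mix, of the Cell Ranger version and of the astrocyte share were chosen after the results were seen; those of Thy1, of the neuron mix, of the oligodendrocyte list and of thinning were written before their own values were known, though all patterns were noticed in these data.

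The effect of M28L against 5xFAD differed between Xist-positive and Y-positive microglia-like nuclei for 99 of 11740 genes, tested as an interaction within libraries by edgeR. Of these, 37 had the more positive effect in Xist-positive nuclei, and 1599 genes had an unadjusted p under 0.05. No gene passed for P522R against 5xFAD (1008 at an unadjusted p under 0.05) or P522R against M28L (607), and DESeq2 was not run on this interaction. Without 5xFAD replicate 2 the 3 counts were 88, 1 and 18, with 55 of the 88 more positive in Xist-positive nuclei. Of 25 stage 2 disease-associated genes 1 was called, with a median interaction of 1.27. Over this list the median log2 ratio of Xist-positive to Y-positive nuclei was −1.44 in 5xFAD replicate 2 and −0.066 in 5xFAD replicate 3. In M28L it was 0.357 and 0.5, so the median interaction rests largely on 5xFAD replicate 2. No cluster share passed such a test (smallest adjusted p = 0.398).

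Xist-positive microglia-like nuclei of 5xFAD replicate 2 held 3 of 454 disease-associated-like nuclei (0.661%, 95% interval 0.137 to 1.92), against 6.80% to 45.4% in the other 11 pools of library and sex. A fault of the whole library is argued against by its Y-positive nuclei, at 20.3% (16.9 to 24.0). A female without the transgenes is a candidate explanation: Thy1, whose promoter cassette carries the 5xFAD transgenes, had 29.7 CPM (25.4 to 34.5) in Xist-positive neuron-like nuclei of that library, against 41.1 or more in the other 11 pools. The mix of neuron clusters does not account for this, since Thy1 was at 0.479 (0.410 to 0.557) of the level expected from that mix, against 0.623 or more elsewhere, and the list of disease-associated oligodendrocyte genes had its lowest ratio of Xist-positive to Y-positive nuclei in the same library (−0.207, against 0.031 to 0.398; 1 library in 6 is lowest by chance). The next lowest Thy1 value was that of the Y-positive nuclei of the same library, the transgene itself was not measured, and no biological explanation was tested.

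Most disease-associated genes were higher in P522R than in M28L microglia-like nuclei (24 of 25 of stage 2 and 21 of 24 of the nuclei list), though none passed over all genes and neither list was called with an estimated correlation (adjusted p = 0.478). A different mix of sexes is argued against by a gap of 17 percentage points or more between the lowest P522R and the highest M28L library in disease-associated-like nuclei within each sex, and the other Cell Ranger version by P522R replicate 2, at 38.2% with the same version as M28L. A difference in depth is argued against by median UMIs per microglia-like nucleus, 3714.5 and 3475 in P522R against 3756 and 3504 in M28L. Thinned nuclei kept a gap of 1.98 stage 2 UMIs between the groups, with 6.52 and 6.24 per nucleus in P522R and 4.15 and 4.26 in M28L. Thinning keeps the expected share of each gene in a nucleus, so it could hardly remove a gap seen in CPM. The shares rest on a cluster of 1947 nuclei defined by genes that differ between the groups, and the ratio of 0.306 without those genes is that of a different cluster of 4074 nuclei, so it does not test the share. An effect of the variant may be the source, as a hypothesis from 2 libraries per group, and differences between the animals pooled were not tested.

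The share of astrocyte-like nuclei was lower in P522R libraries. Loss of astrocytes when barcodes were selected or named is argued against by astrocyte transcripts in oligodendrocyte-like nuclei, which were lower as well (median −1.29 against 5xFAD), and the Cell Ranger version by P522R replicate 2, at 3.34%, below all 4 libraries of the other groups. The sort or the tissue taken may still be the source: endothelial-like, pericyte-like and fibroblast-like nuclei were lower too, with ratios of mean shares of P522R to 5xFAD up to 0.489 (0.267 for astrocytes). An effect of the variant on astrocytes stays open and cannot be separated from the sort by these values.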

How the results depend on the processing

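Tests of single-sex nuclei, of single microglia clusters and of clustering without genes of unadjusted p under 0.05 were chosen after the data were seen. With 2 libraries per group, counts of genes move widely between settings: the 5xFAD libraries differ from each other in microglia by a chi-square over degrees of freedom of 8.40, against 3.49 in M28L and 2.48 in P522R, and set much of the spread. RLE size factors, a minimum count of 50, at least 1000 UMIs per nucleus, doublets kept and the other resolution left the microglia counts at 1, 0 and 1 for M28L against 5xFAD, P522R against 5xFAD and P522R against M28L. In this order, DESeq2 called 7, 12 and 47 genes. No low-count filter gave 203, 528 and 415, of which the filter had removed 0, 10 and 4: without it the prior degrees of freedom went from 5.94 to infinite, so that the spread is pooled fully. The 4 libraries compared gave 0, 0 and 293. A replicate term gave 30, 135 and 65. Only 2 replicate numbers exist and the labels do not say what they share; residuals of same-numbered libraries correlated across genes by 0.311, 0.159 and 0.203 in microglia, and by 0.124 to 0.434 in all 15 pairs of groups over 5 cell types, so a shared effect of the number is not excluded. Leaving out 1 library gave 0 to 143, 0 to 833 and 0 to 314. Xist-positive nuclei alone gave 0, 0 and 0, and Y-positive nuclei 48, 0 and 52. Cluster 0 (homeostatic-like) gave 2, 10 and 6, cluster 1 (unnamed) 10, 2 and 23, cluster 2 (disease-associated-like) 60, 3 and 59, and cluster 3 (interferon-like) 5, 20 and 24. Beyond these constructions the cause was not tested. Summed over the other cell types, edgeR called 12, 27 and 4, DESeq2 267, 248 and 106, no filter 2128, 2993 and 1006, and a replicate term 2112, 2080 and 266. Leaving out 1 library gave 1 to 146, 12 to 337 and 0 to 219. Of 31 lists in microglia 13, 16 and 12 were called with the preset correlation, 0, 2 and 2 with an estimated one and 0, 1 and 1 by fry. For P522R against M28L the estimates included 0.765 (stage 2), 0.432 (homeostatic microglia) and 0.338 (cholesterol synthesis). Others lay near the preset value, such as 0.018 for phagocytic receptors. Where the estimate lies far above the preset value, a call with the preset value overstates the evidence. Lists with an estimate near or below it lost calls as well, such as TREM2 and PLCG2 signalling in M28L against 5xFAD (−0.002). A call lost there does not come from a higher correlation. In other types 40, 69 and 61 lists were called, 0, 0 and 0 with an estimated correlation (smallest adjusted p = 0.668) and 0, 0 and 0 by fry (0.258).

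Passing cell type shares numbered 0, 7 with a replicate term and 0 to 8 without 1 library. Passing microglia cluster shares are not counted for fits without 1 library, since the library left cannot show the spread within its group. Those that passed with all libraries numbered 1. They numbered 0 with at least 1000 UMIs, doublets kept, the other resolution or clustering without genes of unadjusted p under 0.05. The disease-associated-like share of P522R against M28L had log2 ratios of 1.707 (adjusted p = 0.0709), 1.335 (0.0737, for 2 clusters of 2509 and 264 nuclei), 1.889 (0.126) and 0.306 (0.862, for a different cluster of 4074 nuclei) in these settings in turn, and 1.651 to 1.90 without 1 library. For M28L against 5xFAD it was 0.164 in the last setting and −1.642 to −0.136 without 1 library, and for P522R against 5xFAD 0.114 to 1.62. Other shares whose sign turned had not passed with all libraries and settings as reported. Microglia shares were 0.007 with a replicate term for M28L against 5xFAD, and T cells −0.086 with doublets kept for P522R against 5xFAD. At the other resolution the homeostatic-like share was 0.621 for M28L and 0.402 for P522R against 5xFAD, and that of all unnamed clusters −0.597 for P522R. These are different clusters, since the homeostatic-like one held 1449 nuclei in place of 3243. An unnamed cluster of 1194 nuclei, with a median log2 fold of homeostatic markers of 0.425, held 618 nuclei of 5xFAD replicate 2. These ratios thus do not test the shares of the first clusters. The cycling-like share of P522R against 5xFAD (31 nuclei in all) was 0.223 with at least 1000 UMIs and 0.04 in clusters without genes of unadjusted p under 0.05.

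Values whose sign turned without 1 library are given as lowest and highest. For M28L against 5xFAD, list medians ran from −0.01 to 0.338 (homeostatic microglia), −0.399 to 0.158 (disease-associated microglia stage 2), −0.577 to 0.06 (disease-associated microglia in nuclei) and −0.314 to 0.167 (glycolysis). Shares ran from −0.437 to 0.05 (OPC), −0.694 to 0.312 (border macrophage), −0.464 to 0.035 (endothelial), −0.445 to 0.493 (microglia), −0.269 to 0.238 (neuron), −0.723 to 0.001 (fibroblast), −0.708 to 0.556 (homeostatic-like cluster) and −0.035 to 0.791 (cycling-like cluster). For P522R against 5xFAD, list medians ran from −0.168 to 0.055 (homeostatic microglia), −0.004 to 0.47 (lipid handling) and −0.345 to 0.087 (disease-associated astrocytes), and shares from −0.118 to 0.345 (T cell), −0.36 to 0.092 (committed oligodendrocyte precursor), −0.64 to 0.312 (microglia), −0.01 to 0.496 (neuron), −1.077 to 0.187 (homeostatic-like), −0.366 to 0.145 (interferon-like) and −0.343 to 0.86 (unnamed cluster). For P522R against M28L they ran from −0.46 to 0.028 (OPC) and −0.591 to 0.138 (microglia), and Plcg2 in microglia from −0.194 to 0.016. The cause was not tested.

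Other values kept their sign without 1 library but moved widely. For M28L against 5xFAD, list medians ran from 0.117 to 0.332 (MHC class I), 0.094 to 0.395 (interferon response), −0.582 to −0.157 (cholesterol synthesis), 0.006 to 0.11 (phagocytic receptors), −0.368 to −0.107 (oxidative phosphorylation), −0.401 to −0.09 (ribosomal proteins), −0.471 to −0.138 (disease-associated astrocytes) and 0.087 to 0.448 (oligodendrocyte transcripts). For P522R against 5xFAD they ran from 0.153 to 0.587 (cholesterol synthesis), −0.411 to −0.107 (oxidative phosphorylation), −0.285 to −0.071 (ribosomal proteins) and 0.11 to 0.367 (myelin), and for P522R against M28L from 0.134 to 0.3 (stage 1), −0.269 to −0.087 (interferon response) and −0.14 to −0.081 (phagocytic receptors). Astrocyte-like shares ran from −2.509 to −1.481 for P522R against 5xFAD and −1.994 to −0.966 against M28L. Genes included Lpl in microglia from 1.283 to 2.233 for P522R against M28L, and Ephb1 from 1.284 to 2.316 and Mobp from 1.277 to 2.107 in committed oligodendrocyte precursors for M28L against 5xFAD. The cause was not tested here either.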

Other observations

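The fits of Xist-positive nuclei, of Y-positive nuclei and of single clusters were chosen after the data were seen. Within the disease-associated-like cluster alone, cholesterol synthesis genes were higher in P522R than in M28L in 12 of 12 measured cases, with a median log2 fold change of 0.70 (adjusted p = 4.34e-09, or adjusted p = 0.255 with an estimated correlation). Homeostatic genes were lower there in 17 of 19 (median −0.34, adjusted p = 7.74e-09, or adjusted p = 0.278 with an estimated correlation). In the homeostatic-like cluster neither list was called (adjusted p = 0.744 and 0.855). Cells were placed in these clusters by genes that also differ between the groups.

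Of the interferon response genes in P522R against M28L, 26 of 27 were lower in Xist-positive microglia-like nuclei (median −0.53, adjusted p = 3.19e-15) and 20 of 23 higher in Y-positive ones (median 0.32, adjusted p = 3.71e-05). With an estimated correlation the lists had adjusted p = 0.608 and 0.292, and the difference between the sexes was not tested for the list. The interferon-like cluster held 18% and 10.5% of Xist-positive nuclei in M28L and 1.32% and 5.84% in 5xFAD, and 3.46% and 4.37% of Y-positive nuclei in M28L and 8.22% and 8.94% in 5xFAD. The interaction for that share had a log2 value of 3.34 (adjusted p = 0.398). In border macrophage-like nuclei 19 of 19 interferon genes were lower in M28L than in 5xFAD (median −0.71, adjusted p = 2.58e-16, or adjusted p = 0.668 with an estimated correlation), and 7 passed adjusted over the list alone. In astrocyte-like nuclei 11 of 11 mitochondrial transcripts were higher in P522R than in 5xFAD (median 1.23, adjusted p = 2.13e-16, or adjusted p = 0.791 with an estimated correlation).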
